A study of Homo sapiens with 14 samples.

How the data were processed

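Polyadenylated RNA of OVCAR-8 cells was sequenced in 14 libraries of 5 groups, with 3 libraries each for Untreated, AB, ASAB and TSEV and 2 for AB-TSEV. Per the labels' protocols, RNA was extracted with TRIzol, checked on a Bioanalyzer, enriched with poly(A) beads and made into stranded libraries with an IDT xGen kit. Groups were taken from the treatment given in the labels.

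Per the submitters' processing notes, the deposited values were made with fastp 0.23.4 and Salmon 1.7.0 on the build GRCh38.p13. What each tool was run for, its options and the annotation release are not given in the sources used here. The deposited files hold, for each of 243577 transcripts, an estimated count of reads in which a read shared by several transcripts is split between them. They also hold deposited TPM, scaled by effective length to a fixed sum per library, per the file headers, and an effective length per transcript. In a library, 35.2% to 38.7% of transcripts had a deposited estimated count that was not whole, with a tolerance of 1e-06.

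Estimated counts were summed over the transcripts of each of 61114 genes, of which 19644 had a coding transcript, and rounded. A gene was kept apart by its identifier where a symbol had several (78 symbols). Genes with too few reads were removed with filterByExpr of edgeR (minimum count 10), which left 18653. Library totals ran from 31041999 to 44106382 reads. CPM, the reads of a gene scaled to an equal total for every library, were computed with TMM factors, and 2 was the prior count wherever a log was taken. Tests used R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 in its robust form, in a single fit of all 14 libraries with 9 residual degrees of freedom and a common biological coefficient of variation of 9.79%. P-values were adjusted by the method of Benjamini and Hochberg within each of 8 comparisons, with calls at 0.05. The TPM served only to weigh transcripts when GC content and length were averaged over a gene, and effective length only for a length offset and for the fragment length it implies.

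A set of 34 gene lists with 761 genes was tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. P-values were adjusted over the lists of a comparison, and lists with fewer than 3 measured genes were not tested. The stress lists were the integrated stress response, unfolded protein response, heat shock, NRF2, hypoxia and glycolysis, p53 targets and apoptosis regulators. Immune lists were type I interferon, interferon-gamma, MHC class I presentation, and NF-kB with inflammatory cytokines. Growth lists were immediate early and MAPK feedback genes, G1/S, G2/M, homologous recombination repair and replication-dependent histones. Lipid lists were cholesterol synthesis and fatty acid synthesis with lipid droplets. Lists for cell identity were epithelial, mesenchymal, tumour surface antigens, ovarian carcinoma, fibroblast, endothelial, B cell, monocyte and macrophage, T cell and cytotoxic effector. Organelle and RNA lists were vesicle and endosome, lysosome, mitochondrially encoded, nuclear respiratory chain, cytosolic ribosomal proteins and nuclear-retained or long noncoding RNA. RIGI was not found under that symbol, so the type I list had 31 of 32 genes. Results for some genes are not reported here.

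Comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. Genes with the largest changes are named if they are protein coding, pass an adjusted p of 0.05, have a mean of at least 1 log2 CPM and show no overlap between the libraries of both groups. Of these the 8 largest rises and falls against Untreated, and the 4 largest in each other comparison, are given. From each list up to 4 members with the smallest p are named if their adjusted p is under 0.05, coding or not. A list with no such member gives its 2 members with the highest CPM. Mitochondrially encoded genes and T cell markers may be named in every comparison. Any other gene named was chosen after the values were seen. Gene locations are from GENCODE 29 matched by identifier, which placed 789 of 791 genes looked up. Interferon genes in the plot of interferon genes were picked after the values were seen.

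Alternatives were RLE factors, DESeq2 1.42.0, no filter, a length offset, coding genes only, fits of the compared groups only, blocks by replicate or tube number, and leaving out each library. A pair of alternatives was added after seeing the data. The first left out Untreated 2 and ASAB 3. The second put an offset for GC content and length into the fit. For this, a smooth trend of mgcv 1.9.3 on GC content and log2 length was fitted per library. It used all tested genes with a known GC content, weighted by mean expression, and the offset was applied to the same genes. Transcripts with a known sequence were 202829 of 243577 and held 94.6% of TPM, and 18228 of 18653 tested genes had a value. The coefficient of variation was then 5.95%. TSEV against ASAB was compared only after the data had been seen.

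The steps were tested on simulated data with 50 changed genes per fold at the depth and spread of these libraries. For AB against Untreated edgeR recovered 0%, 58%, 58% and 86% of genes changed 1.2, 1.5, 2 and 4 times and called 3 of 18453 unchanged genes. For AB-TSEV against Untreated it recovered 0%, 52%, 72% and 90% and called 6. Camera called 1 of 1 shifted list and 0 of 32 unshifted ones. With a GC and length trend laid over AB-TSEV against ASAB, 1222 of 18453 unchanged genes were called without the offset and 8 with it.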

Results

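RNA sequencing measured polyadenylated RNA of OVCAR-8 cells, a human ovarian cancer line, after treatment with an antibody that binds these cells, with small extracellular vesicles (sEVs) shed by CD8+ T cells, or with both joined. The 14 libraries fall into 5 groups. Untreated cells (n = 3) received nothing, AB cells (n = 3) the free antibody, and ASAB cells (n = 3) the antibody carrying a polyethylene glycol spacer and a BODIPY anchor for membranes. TSEV cells (n = 3) received sEVs alone and AB-TSEV cells (n = 2) received sEVs decorated with the antibody. The series states its aim as the effect of these treatments on the RNA profile. The antibody's target, the doses and the time of exposure are not given in the sources used here.

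Read totals per library were 36783670, 37980133 and 32523866 for Untreated 1 to 3, 37213518, 41425169 and 42237828 for AB, and 41894519, 40042831 and 40597098 for ASAB. They were 42872155, 33835966 and 44106382 for TSEV and 31041999 and 31400520 for AB-TSEV. Between 23373 and 24299 genes had reads in a library. Genes of the mitochondrial genome took 4.89% to 6.61% of reads, with the highest share in Untreated 3 and the lowest in ASAB 3. A count of 0 over a whole group allows up to 0.0274 CPM in Untreated, 0.0255 in AB, 0.0242 in ASAB, 0.0248 in TSEV and 0.0486 in AB-TSEV. Such floors, and any interval on a count, cover counting error only. Values below are mean CPM ± SD over the libraries of a group, and changes are log2 fold changes from edgeR with p adjusted over 18653 genes. The p-values measure spread between libraries, and whether the libraries of a group came from separate cultures is not stated.

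The libraries fall into a pair of sets by the numbers on the submission sheet. Numbers 1 to 9 are the TSEV, ASAB and AB libraries, with an implied fragment length of 191 to 196 nt, and numbers 27 to 31 are the Untreated and AB-TSEV libraries, with 212 to 229 nt. AB-TSEV against Untreated, ASAB against AB and TSEV against AB stay within a set. In the other 5 comparisons the set changes with the treatment, so set and group cannot be told apart there. Part of the difference between sets follows the GC content and length of genes. Over 10579 well expressed genes, which are not independent replicates, Spearman's rho between fold change and GC content was 0.82 for AB-TSEV against ASAB and 0.75 for AB-TSEV against TSEV. It was -0.47 for ASAB and for TSEV against Untreated, -0.34 for AB against Untreated, and between -0.04 and 0.1 in the 3 comparisons within a set. Single libraries also followed GC content and length. Against the rest of its own group, Untreated 2 had rho of -0.66 with GC content and 0.72 with length, and ASAB 3 had -0.17 and -0.67. Values with an offset for GC content and length are therefore printed for the comparisons and for some of the lists that it moves most.

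**Figure D1:**
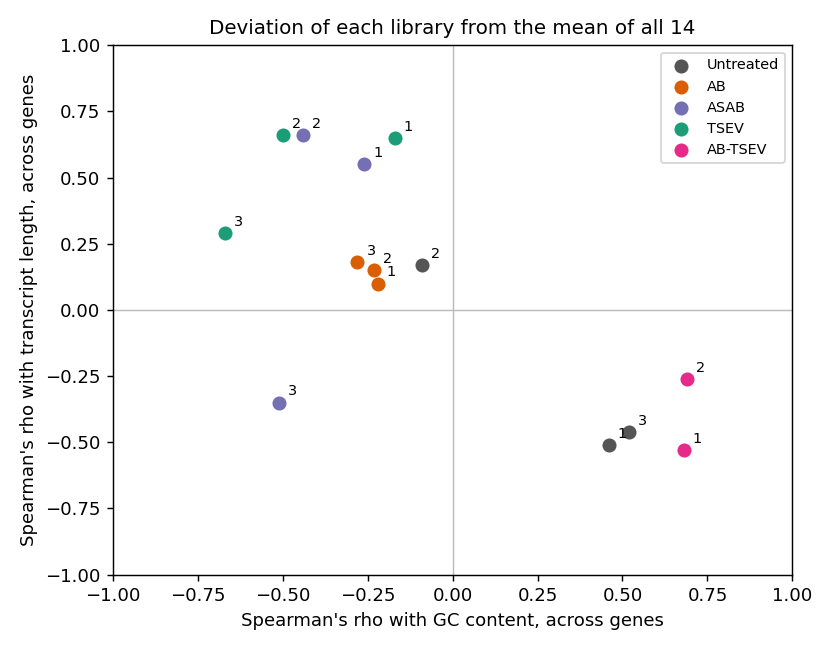
Each point is 1 of the 14 libraries, numbered by replicate and coloured by group. Its deviation from the mean of all libraries is correlated across 10579 genes with GC content (x axis, Spearman's rho) and with transcript length (y axis, Spearman's rho). AB-TSEV 1 and 2 lie at 0.68 and 0.69 on the GC axis and TSEV 3 at -0.67, while Untreated 2 and ASAB 3 lie away from their groups.

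AB against Untreated asks what the free antibody alone does to the cells. Genes of the integrated stress response, which eIF2-alpha kinases and ATF4 switch on when amino acids or protein folding fail, were among the largest falls. INHBE, an ATF4 target on chromosome 12 (GRCh38 57452323 to 57459280), went from 95.7 ± 1.66 CPM in Untreated to 0.502 ± 0.0209 in AB, a log2 fold change of -7.57 (SE 0.165, adjusted p = 2.03e-14). The asparagine synthetase gene ASNS (chromosome 7, 97852118 to 97872542) went from 314.2 ± 15.1 to 13.0 ± 0.642 CPM, the glutathione-degrading enzyme gene CHAC1 (chromosome 15, 40952962 to 40956519) from 114.0 ± 17.8 to 2.62 ± 0.23, and the pseudokinase gene TRIB3 (chromosome 20, 362835 to 397559) from 394 ± 42.8 to 16.8 ± 0.674. ASNS overlaps the annotated gene AC079781.5, so reads of the pair may be shared. All 24 genes of the integrated stress response list fell, 24 also when adjusted over the list alone (median log2 fold change -2.56, adjusted p = 4.92e-74, and 0.000653 with an estimated correlation). NUPR1, also of this list, had 1.14 ± 0.509 CPM in Untreated and no read in AB, so its fold change is only a bound set by the AB floor.

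Genes that respond within minutes to growth factors, and the cytokines that NF-kB drives, fell with them. The transcription factor gene EGR1 (chromosome 5, 138465490 to 138469315) went from 621 ± 98.8 to 6.95 ± 0.364 CPM, a log2 fold change of -6.48, FOS (chromosome 14, 75278774 to 75282230) from 65.0 ± 5.96 to 1.53 ± 0.119, and FOSB (chromosome 19, 45467995 to 45475179) from 58.1 ± 6.21 to 1.31 ± 0.428. The chemokine genes CXCL8 (chromosome 4, 73740506 to 73743716) and CXCL2 (chromosome 4, 74097035 to 74099293) went from 34.2 ± 5.93 to 0.695 ± 0.0698 and from 83.9 ± 3.25 to 1.82 ± 0.189 CPM. DDIT4, an inhibitor of mTORC1 (chromosome 10, 72273920 to 72276036), went from 271 ± 20.5 to 5.98 ± 0.665 CPM. Of the 24 measured immediate early and MAPK feedback genes, 18 fell and 2 rose, 18 and 2 also when adjusted over the list alone (median -1.22, adjusted p = 4.66e-22). JUN fell to 175 ± 2.01 from 638 ± 22.8 CPM and DUSP1 to 139 ± 3.81 from 506 ± 24.7. Of 27 NF-kB and inflammatory cytokine genes 24 fell and 0 rose, 24 when adjusted over the list alone (median -1.50, adjusted p = 4.8e-31), among them IL1A (log2 fold change -4.29), CXCL1 (-3.53) and IL6 (-2.96). Of 21 p53 target genes, 9 fell and 7 rose, 10 and 7 when adjusted over the list alone (median -0.19, adjusted p = 2.21e-05). SESN2 (-3.54), BBC3 (-3.06) and CDKN1A (-1.36) fell in that list. SESN2 is also in the integrated stress response list, so these list results are not independent.

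Chaperone and DNA replication genes rose. The heat shock protein genes HSPA1A (chromosome 6, 31815464 to 31817946) and HSPA1B (chromosome 6, 31827735 to 31830255) went from 137 ± 11.5 to 924 ± 21.2 and from 99.7 ± 5.16 to 591 ± 15.2 CPM. Their sequences are nearly identical, so the division of reads between them is uncertain. In the heat shock list 19 of 20 genes rose and 1 fell, 19 and 1 when adjusted over the list alone (median 1.21, adjusted p = 4.55e-29), with DNAJA1 at 307 ± 7.94 against 71.0 ± 0.629 CPM. The transferrin receptor gene TFRC (chromosome 3, 196027183 to 196082189), which takes up iron, rose from 19.9 ± 4.41 to 151 ± 5.01 CPM (log2 fold change 2.92, SE 0.131, adjusted p = 3.07e-11). ALPP, TAGLN, CAVIN2, MT-ND6 and ENSG00000275740 rose with log2 fold changes of 2.87, 2.68, 2.62, 2.23 and 2.40. ALPP is nearly identical to other alkaline phosphatase genes, and ENSG00000275740 overlaps RBM27 and POU4F3, which leaves both values uncertain. G1/S and DNA replication genes rose in 22 of 24 cases with 1 fall, the same when adjusted over the list alone (median 1.02, adjusted p = 4.26e-20), with UHRF1 at 375 ± 2.45 against 123 ± 3.23 CPM and FEN1 at 209 ± 5.28 against 66.7 ± 3.64.

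The test called 10861 of 18653 genes in AB against Untreated, 5333 up and 5528 down, with 842 and 2079 of them at least 2 times apart. With the GC content and length offset it called 11764, of which 9454 were called in both fits in the same direction and 23 in opposite directions. The stress response, heat shock, immediate early, NF-kB, p53 and G1/S calls held with an estimated correlation (highest adjusted p = 0.0105). Of 13 list calls 6 held in this way, and among the others were type I interferon (16 rose and 4 fell of 27, the same adjusted over the list alone, adjusted p = 0.00501, and 0.172 with an estimated correlation), G2/M and mitosis (18 and 1 of 26, 1.6e-05 and 0.297) and homologous recombination repair (16 and 1 of 22, 2.21e-05 and 0.256). IFIT1 rose to 22.9 ± 1.45 from 7.1 ± 0.518 CPM in the first of these lists. The interferon-gamma list was not called, with 3 genes up and 10 down of 19, 4 and 10 adjusted over the list alone, at an adjusted p of 0.211. Its member WARS1 fell to 89.0 ± 1.0 from 246 ± 5.57 CPM.

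**Figure D2:**
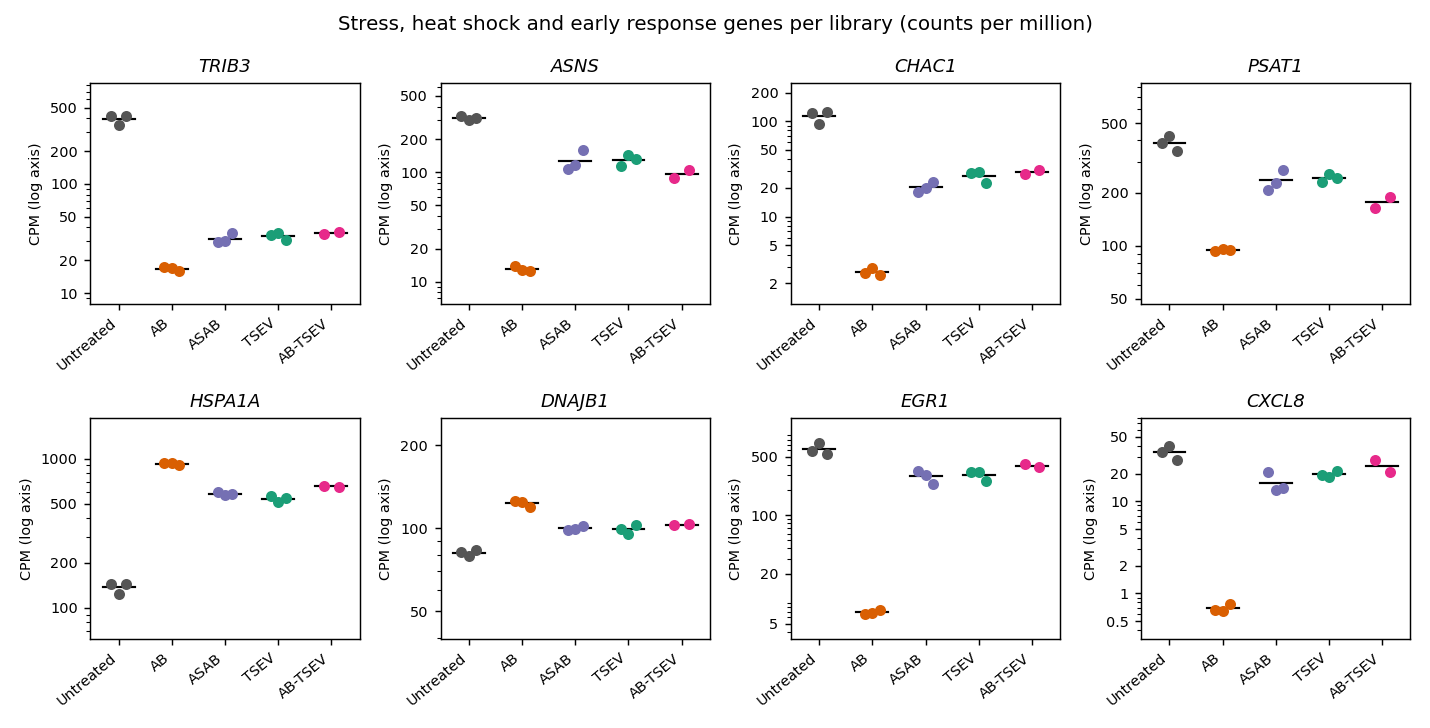
CPM of TRIB3, ASNS, CHAC1, PSAT1, HSPA1A, DNAJB1, EGR1 and CXCL8 in the 5 groups on log axes, with points for libraries and a bar for the group mean. Untreated lies above all treated groups for ASNS (314.2 CPM against 128, 129.5, 96.5 and 13.0), and AB lies apart from the other treated groups for EGR1 (6.95 CPM).

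ASAB against Untreated asks the same of the antibody once it carries the spacer and anchor. The stress response genes were lower again, by less. INHBE was at 5.98 ± 0.594 CPM against 95.7 ± 1.66 (log2 fold change -4.00) and TRIB3 at 31.7 ± 3.23 against 394 ± 42.8 (-3.64, SE 0.102, adjusted p = 1.08e-12). SESN2 (chromosome 1, 28259527 to 28282491), DDIT4, BEST1, CXCL2 and IL20RB fell by 3.02, 2.91, 2.74, 2.65 and 2.65 on the log2 scale, IL20RB with an overlap with NCK1. All 24 stress response genes fell, the same adjusted over the list alone (median -1.38, adjusted p = 2.36e-54). NF-kB genes fell in 22 of 27 cases, 22 adjusted over the list alone (median -0.84, adjusted p = 4.68e-17), with RELB at 18.4 ± 2.12 against 55.7 ± 6.7 CPM. Of 24 immediate early genes 19 fell and 0 rose, 19 and 1 adjusted over the list alone (median -0.75, adjusted p = 3.35e-10). FOS itself had 69.1 ± 13.0 CPM in ASAB and 65.0 ± 5.96 in Untreated. Of 21 p53 targets 10 fell and 6 rose, the same adjusted over the list alone (median -0.15, adjusted p = 3.72e-05), with GDF15 at 0.235 ± 0.0342 against 5.64 ± 1.17 CPM.

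Chaperones rose here too, and with them the enzymes that make cholesterol. HSPA1A reached 583 ± 12.2 CPM and the related HSPA2 (chromosome 14, 64535905 to 64546173) 21.4 ± 0.282 against 4.46 ± 0.427. In the heat shock list 17 of 20 rose and 1 fell, 18 and 1 adjusted over the list alone (median 0.62, adjusted p = 2.49e-22). INSIG1, the sterol sensor partner of SREBP cleavage, rose to 188 ± 9.19 from 68.7 ± 4.86 CPM and HMGCS1, an early enzyme of the pathway, to 293 ± 2.86 from 96.8 ± 13.0. Cholesterol synthesis genes rose in 16 of 26 cases and fell in 3, 17 and 4 adjusted over the list alone (median 0.29, adjusted p = 9.42e-08). Fatty acid and lipid droplet genes rose in 11 of 22 and fell in 3, the same adjusted over the list alone (adjusted p = 0.0147, and 0.191 with an estimated correlation). ALPP, ZBED6, HSPA1B and TFRC rose by 3.02, 2.30, 2.12 and 2.10, ZBED6 lying within ZC3H11A. ENSG00000260537 had 6.01 against 1.23 CPM but overlaps the DDX19 genes and lost its call in several other settings. MT-ND6 had 295 ± 10.4 CPM in ASAB and 137 ± 15.8 in Untreated.

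The test called 8196 genes here, 3977 up and 4219 down, 380 and 795 of them at least 2 times apart. With the GC content and length offset it called 9042, of which 6408 were called in both fits in the same direction and 18 in opposite directions. The stress response, NF-kB, immediate early, p53, heat shock and cholesterol calls held with an estimated correlation (highest adjusted p = 0.0259). The G1/S call (19 up and 2 down of 24, the same adjusted over the list alone, adjusted p = 8.87e-07) was at 0.184 and the G2/M call (16 and 4 of 26, 0.000866) at 0.498 with an estimated correlation.

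TSEV against Untreated asks what sEVs of CD8+ T cells do to the cells without the antibody. Here an interferon programme rose. The interferon-induced GTPase gene GBP1 went from 12.1 ± 0.997 to 43.8 ± 1.31 CPM (log2 fold change 1.85, adjusted p = 1.67e-10). ERAP1, which trims peptides for MHC class I, went from 18.1 ± 3.41 to 42.6 ± 1.43 CPM, and OAS3, which senses viral RNA, from 8.07 ± 1.42 to 21.4 ± 0.769. Interferon-gamma response genes rose in 10 of 19 cases and fell in 1, the same adjusted over the list alone (median 0.41, adjusted p = 0.000303, and 0.0144 with an estimated correlation). Type I interferon genes rose in 14 of 27 and fell in 2, 15 and 2 adjusted over the list alone (median 0.38, adjusted p = 1.66e-06, and 0.0195 with an estimated correlation). Rises in this list were not particular to TSEV. With the GC content and length offset 17 rose and 2 fell here, 15 and 5 in AB, 13 and 4 in ASAB and 13 and 3 in AB-TSEV against Untreated. Of these, only TSEV passed in camera with an estimated correlation (adjusted p = 0.0255). MHC class I antigen presentation genes rose in 16 of 21, 18 adjusted over the list alone (median 0.58, adjusted p = 7.68e-09, and 0.0618 with an estimated correlation). All 21 rose with the GC content and length offset, at 0.00804 with an estimated correlation. HLA genes are highly polymorphic, so their read division is uncertain. TAP1, which rose to 143 ± 12.4 from 86.3 ± 2.31 CPM, lies within PSMB9 on the other strand.

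The stress programme of Untreated was lower in this group as well. INHBE (-3.72), TRIB3 (-3.56), IL20RB (-2.83), SESN2 (-2.68), BEST1 (-2.56) and LURAP1L (-2.54) were among the largest falls, with TXNIP (chromosome 1, 145992435 to 145996600), a brake on glucose uptake, at 30.2 ± 4.48 against 187 ± 13.7 CPM. All 24 stress response genes fell, the same adjusted over the list alone (median -1.31, adjusted p = 1.12e-44). Of 24 immediate early genes 18 fell, 20 adjusted over the list alone (median -0.68, adjusted p = 7.17e-10). Of 21 p53 targets 11 fell and 6 rose, 11 and 7 adjusted over the list alone (median -0.38, adjusted p = 0.000103). NF-kB genes fell in 15 of 27 and rose in 1, the same adjusted over the list alone (median -0.27, adjusted p = 7.13e-07, and 0.111 with an estimated correlation). Heat shock genes rose in 18 of 20 cases and fell in 1, the same adjusted over the list alone (median 0.68, adjusted p = 4.64e-22), with HSPA1A at 539.7 ± 24.4 CPM, HSPA1B at 404 ± 5.19 and HSPA2 at 19.0 ± 1.8. TFRC (2.27) and the taurine transporter gene SLC6A6 (1.93, chromosome 3, 14402576 to 14489349) also rose, as did ENSG00000275740 (2.45), ZBED6 (2.41) and ENSG00000260537 (2.10) with the overlaps named above. Cholesterol synthesis genes rose in 14 of 26 and fell in 4, 16 and 5 adjusted over the list alone (adjusted p = 2.64e-06, and 0.051 with an estimated correlation), with INSIG1 at 186 ± 7.36 CPM.

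The test called 8739 genes in TSEV against Untreated, 4206 up and 4533 down, 383 and 971 of them at least 2 times apart. With the GC content and length offset it called 9316, of which 6585 were called in both fits in the same direction and 59 in opposite directions. T cell transcripts stayed low. CD3E and IFNG had no read in any library, and 36 of 40 T cell and cytotoxic marker genes, without those that OVCAR-8 itself clearly expresses, summed to 1.88 ± 0.234 CPM in TSEV, 1.54 ± 0.112 in AB, 1.87 ± 0.0938 in ASAB, 2.56 ± 0.282 in AB-TSEV and 3.01 ± 0.422 in Untreated. CD8A, which OVCAR-8 expresses, had 0.976 ± 0.119 CPM in TSEV against 3.04 ± 0.217 in Untreated.

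AB-TSEV against Untreated asks for the effect of the antibody-decorated vesicles and compares libraries of a single set (n = 2 and 3). INHBE was at 5.97 ± 1.22 CPM against 95.7 ± 1.66 (log2 fold change -4.00), TRIB3 at 35.3 ± 1.14 against 394 ± 42.8 (-3.48) and TXNIP at 25.6 ± 2.11 against 187 ± 13.7 (-2.87). SPX (chromosome 12, 21526307 to 21541249), IL20RB, DDIT4 and LURAP1L fell by 2.83, 2.78, 2.67 and 2.63. All 24 stress response genes fell, the same adjusted over the list alone (median -1.51, adjusted p = 2.58e-67, and 0.00103 with an estimated correlation). STC2, a secreted glycoprotein of this response, had 172 ± 9.29 CPM against 733 ± 10.6. Cholesterol synthesis genes rose in 17 of 26 cases, 18 adjusted over the list alone (median 0.48, adjusted p = 7.52e-15, and 0.00551 with an estimated correlation), with HMGCS1 at 257 ± 13.4 against 96.8 ± 13.0 CPM and the lanosterol synthase gene LSS at 211 ± 2.94 against 102 ± 0.878. Heat shock genes rose in 16 of 20, the same adjusted over the list alone (median 0.66, adjusted p = 3.27e-26), with HSPA1A at 653 ± 8.97 CPM, HSPA1B at 428 ± 1.65 and HSPA2 at 23.5 ± 1.45. ALPP (3.58), FAM167B (2.16), FGFBP1 (2.15), NID2 (1.97) and TP53INP1 (1.88) also rose.

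Interferon genes moved in both directions here, and their difference from bare vesicles is tested in AB-TSEV against TSEV. WARS1, an interferon-gamma target, fell to 138 ± 6.38 from 246 ± 5.57 CPM, and it was also below Untreated in AB and in ASAB (142 ± 10.9 CPM). Its fall does not stand for the interferon-gamma list, which was not called here. Type I interferon genes rose in 10 of 27 cases, with 11 up and 2 down adjusted over the list alone (adjusted p = 0.0361, and 0.267 with an estimated correlation). Interferon-gamma genes rose in 4 and fell in 4 of 19, 6 and 4 adjusted over the list alone (adjusted p = 0.32). MHC class I genes rose in 6 of 21, the same adjusted over the list alone (adjusted p = 0.0514). NF-kB genes fell in 15 and rose in 3 of 27, 16 and 3 adjusted over the list alone (median -0.53, adjusted p = 1.09e-06, and 0.149 with an estimated correlation). Immediate early genes fell in 13 and rose in 1 of 24, the same adjusted over the list alone (adjusted p = 2.71e-06, and 0.046 with an estimated correlation). Of 21 p53 targets 10 fell and 5 rose, 11 and 7 adjusted over the list alone (adjusted p = 0.000523, and 0.0194 with an estimated correlation), and 8 rose with the offset. Fatty acid and lipid droplet genes rose in 10 and fell in 1 of 22, the same adjusted over the list alone (adjusted p = 0.000442, and 0.0697 with an estimated correlation). In the G1/S list 13 of 24 rose, 15 adjusted over the list alone (adjusted p = 4.19e-06, and 0.189 with an estimated correlation).

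The test called 4988 genes in AB-TSEV against Untreated, 2493 up and 2495 down, 257 and 571 of them at least 2 times apart. The count was 2635 without AB-TSEV 1 and 3144 without AB-TSEV 2, and 2571 in a fit of these groups only. An offset for GC content and length gave 7670.

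Against Untreated, 3036 genes were called in the same direction in all 4 treated groups, 1415 up and 1621 down. Independent lists would share 34 and 41, and simulated data with no treatment effect but the same shared controls gave 0 and 0. The simulated data held no difference between library sets and no GC content or length trend, so they cover the shared controls only. INHBE, TRIB3 and IL20RB fell, and HSPA1A and HSPA2 rose, in each group. Fold changes of ASAB and TSEV had r = 0.809 across genes (0.509 in the simulated data) and a covariance of 0.392 (0.0468 simulated), with 3504 genes up in both, 3681 down in both and 5 opposed, where independent lists would share 897 and 1025. For AB and AB-TSEV r was 0.551 (0.426 simulated) and the covariance 0.333 (0.0466 simulated), with 1820 up in both, 1933 down in both and 183 opposed, where independent lists would share 713 and 739. AB shared 3358 rises and 3460 falls with ASAB, where independent lists would share 1137 and 1250. Part of the excess may come from the shared Untreated libraries, whose spread alone gives a covariance of 0.0417. The library set also changes in AB, ASAB and TSEV against Untreated, and its part in the overlap was not tested. The overlap was 2403, 4388 and 2459 genes without Untreated 1, 2 and 3. It was 1780 with fits of the compared groups only, 5155 with the GC content and length offset and 5234 with Untreated 2 and ASAB 3 left out.

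ASAB against AB asks what the spacer and anchor change in the antibody's effect, within a library set (n = 3 and 3). TSEV cells, which received no antibody, differed from AB in much the same way, with FOS up by 5.33 and EGR1 by 5.45. TSEV against ASAB, compared after the data were seen, called 47 genes. Differences shared in this way do not tell an effect of the spacer and anchor from a difference particular to the AB group. Immediate early genes that were near silence in AB were expressed in ASAB. FOS had 69.1 ± 13.0 against 1.53 ± 0.119 CPM (log2 fold change 5.49), EGR1 291 ± 51.2 against 6.95 ± 0.364 (5.39), FOSB 30.6 ± 14.1 against 1.31 ± 0.428 (4.56) and CXCL8 15.9 ± 4.05 against 0.695 ± 0.0698 (4.51). Of 24 immediate early genes 10 rose and 4 fell, 12 and 4 adjusted over the list alone (median 0.16, mean 0.93, adjusted p = 1.39e-21). NF-kB genes rose in 18 of 27, 19 adjusted over the list alone (median 0.78, adjusted p = 4.12e-28), with IL6 at 42.6 ± 6.46 against 10.9 ± 0.668 CPM and IL1B at 10.9 ± 1.15 against 2.47 ± 0.207. Stress response genes rose in 22 of 24 and fell in 1, the same adjusted over the list alone (median 0.94, adjusted p = 1.83e-51), with ASNS at 128 ± 27.9 against 13.0 ± 0.642 CPM and the cystine transporter gene SLC7A11 at 100.4 ± 10.8 against 15.5 ± 0.449. Cholesterol synthesis genes rose in 20 of 26, 22 adjusted over the list alone (median 0.42, adjusted p = 1.54e-14), with INSIG1 at 188 ± 9.19 against 70.6 ± 1.32 CPM.

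Replication, repair and chaperone genes were lower in ASAB than in AB. G1/S genes fell in 22 of 24 cases, the same adjusted over the list alone (median -0.57, adjusted p = 1.55e-24), with RRM2 at 126 ± 12.6 against 247 ± 7.04 CPM. Homologous recombination genes fell in 16 of 22, the same adjusted over the list alone (median -0.48, adjusted p = 1.13e-11), and heat shock genes in 17 of 20, 19 adjusted over the list alone (median -0.44, adjusted p = 3.27e-15), with BAG3 at 44.8 ± 0.713 against 70.5 ± 0.487 CPM. TAGLN, an actin-binding protein gene of contractile cells (chromosome 11, 117199321 to 117204782), fell to 31.4 ± 4.07 from 80.4 ± 1.56 CPM, and FAM111B to 54.6 ± 3.37 from 123 ± 2.87. TNFRSF8 (-1.38) and PRR22 (-1.30) fell from low levels, PRR22 with an overlapping neighbour. Mitochondrially encoded genes fell in 10 of 13, 11 adjusted over the list alone (median -0.44, adjusted p = 9.35e-06, and 0.255 with an estimated correlation), among them MT-ND6 (-1.12). Type I interferon genes fell in 11 and rose in 4 of 27, 12 and 5 adjusted over the list alone (adjusted p = 0.0182, and 0.183 with an estimated correlation). Of 21 p53 targets 9 rose and 2 fell, 10 and 2 adjusted over the list alone (adjusted p = 0.0135, and 0.0522 with an estimated correlation).

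The test called 4766 genes in ASAB against AB, 2447 up and 2319 down, 547 and 94 of them at least 2 times apart. The immediate early, NF-kB, stress response, cholesterol, G1/S, repair and heat shock calls held with an estimated correlation (highest adjusted p = 0.0464). The count was 7472 with the GC content and length offset and 7158 with Untreated 2 and ASAB 3 left out.

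TSEV against AB sets bare vesicles beside the free antibody within a library set (n = 3 and 3). Interferon-gamma targets were higher in TSEV than in AB. This comparison alone does not tell a rise with vesicles from a fall with the free antibody. WARS1 was also lower in AB than in Untreated, as given above. WARS1, a tryptophan tRNA synthetase gene that interferon-gamma induces (chromosome 14, 100333788 to 100376805), had 285 ± 1.1 against 89.0 ± 1.0 CPM (log2 fold change 1.68, adjusted p = 1.42e-10), GBP2 14.4 ± 0.963 against 4.83 ± 0.204, and the immunoproteasome gene PSMB9 (chromosome 6, 32844136 to 32859585) 60.1 ± 5.99 against 25.1 ± 1.75. Interferon-gamma genes rose in 12 of 19 cases, 14 adjusted over the list alone (median 0.68, adjusted p = 1.1e-14, and 0.000397 with an estimated correlation). MHC class I genes rose in 16 and fell in 1 of 21, 17 and 1 adjusted over the list alone (median 0.60, adjusted p = 5.65e-13, and 0.0195 with an estimated correlation), with TAP1 (chromosome 6, 32845209 to 32853978) up by 1.04. Type I interferon genes were divided, with 10 up and 9 down of 27, the same adjusted over the list alone (median 0.04, adjusted p = 0.43).

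EGR1 (304 ± 41.8 CPM, log2 fold change 5.45), FOS (61.8 ± 5.35, 5.33), CXCL8 (19.6 ± 1.54, 4.81) and FOSB (22.5 ± 3.26, 4.11) were above AB here as in ASAB, and IL6 had 84.0 ± 5.63 against 10.9 ± 0.668 CPM. NF-kB genes rose in 22 of 27, the same adjusted over the list alone (median 1.23, adjusted p = 1.05e-47). Stress response genes rose in 22 and fell in 1 of 24, 23 and 1 adjusted over the list alone (median 1.17, adjusted p = 5.61e-58), and immediate early genes rose in 10 and fell in 4, the same adjusted over the list alone (median 0.24, mean 0.91, adjusted p = 5.92e-20). Cholesterol synthesis genes rose in 19 and fell in 1 of 26, the same adjusted over the list alone (median 0.43, adjusted p = 3.25e-11). G1/S genes fell in 22 of 24, the same adjusted over the list alone (median -0.56, adjusted p = 3.41e-21), and heat shock genes in 17 of 20, 18 adjusted over the list alone (median -0.46, adjusted p = 1.35e-13). TAGLN fell to 29.2 ± 4.54 from 80.4 ± 1.56 CPM. ALPP fell to 2.01 from 4.96 CPM, a call lost with a length offset, NPIPA5 (-1.32) has near-identical copies, and MKKS as annotated under a further identifier (-1.98) overlaps MKKS itself. The test called 5188 genes, 2629 up and 2559 down, 551 and 191 of them at least 2 times apart. With the GC content and length offset it called 7732, of which 5116 were called in both fits in the same direction. The lists above with p-values under the threshold held with an estimated correlation (highest adjusted p = 0.0195). With Untreated 2 and ASAB 3 left out of the fit the count was 7809.

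AB-TSEV against TSEV asks what the antibody adds to the vesicles, across library sets (n = 2 and 3). Some interferon genes were lower with decorated than with bare vesicles. WARS1 had 138 ± 6.38 against 285 ± 1.1 CPM (log2 fold change -1.04, adjusted p = 8.76e-06), PSMB9 31.4 ± 3.86 against 60.1 ± 5.99 (-0.94) and ERAP1 20.2 ± 2.97 against 42.6 ± 1.43 (-1.08). Interferon-gamma genes fell in 6 and rose in 2 of 19, the same adjusted over the list alone (median -0.22, adjusted p = 0.000118, and 0.0336 with an estimated correlation). In the fit with the offset 7 fell and 0 rose (median -0.40, 0.000608 with an estimated correlation). MHC class I genes fell in 8 of 21, the same adjusted over the list alone (median -0.26, adjusted p = 1.47e-08, and 0.132 with an estimated correlation), and in 18 with the offset (median -0.45, 0.000507 with an estimated correlation). Type I interferon genes fell in 8 of 27, 9 adjusted over the list alone (adjusted p = 0.000118, and 0.12 with an estimated correlation), and in 8 with the offset (0.0256 with an estimated correlation). Epithelial genes rose in 9 and fell in 2 of 20, 10 and 3 adjusted over the list alone (median 0.40, adjusted p = 0.00536, and 0.266 with an estimated correlation), and ovarian carcinoma genes rose in 5 of 8, 6 adjusted over the list alone (adjusted p = 0.00276, and 0.266 with an estimated correlation). The offset ended the calls of genes in these last lists, though both lists stayed called in the same direction at the preset correlation.

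The test called 3825 genes, 1902 up and 1923 down, 151 and 104 of them at least 2 times apart, and 1118 with the GC content and length offset, 464 up and 654 down. The count rested on single libraries, with 17 genes without AB-TSEV 1, 1622 without AB-TSEV 2, 443 without TSEV 2 and 589 without TSEV 3. With the offset it was 87 and 577 without AB-TSEV 1 and 2, and 813, 474 and 533 without TSEV 1, 2 and 3. Among single genes ALPP (8.07 against 2.01 CPM, log2 fold change 1.99, adjusted p = 0.00802) and ADORA2A (7.46 against 3.49, 1.10) rose, each with a near copy or overlap. ENSG00000259132 (1.16), ENSG00000263020 (1.14), ENSG00000275740 (-2.31) and CCDC144A (-2.11) lost their calls with the offset, at adjusted p of 0.061, 0.134, 0.094 and 0.0717. ZBED6 (-2.24) kept it at 0.0156, and ENSG00000284906 (-2.03) overlaps ARHGAP11B.

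AB-TSEV against ASAB sets the modified antibody on vesicles beside the modified antibody alone, again across sets (n = 2 and 3). Some inflammatory genes were higher on vesicles. IL6 had 77.1 ± 10.7 against 42.6 ± 6.46 CPM (log2 fold change 0.86, adjusted p = 0.00367), CXCL1 8.4 ± 1.23 against 4.59 ± 0.545 (0.87, adjusted p = 0.0068) and the adhesion molecule gene ICAM1 243 ± 4.8 against 176 ± 18.0 (0.46). NF-kB genes rose in 13 of 27, 16 adjusted over the list alone (median 0.46, adjusted p = 2.36e-09, and 0.193 with an estimated correlation). In this list 6 rose with the GC content and length offset, at 0.0706 with an estimated correlation. Interferon-gamma genes rose in 3 of 19, the same adjusted over the list alone (median 0.30, adjusted p = 0.0217, and 0.193 with an estimated correlation), and MHC class I genes rose in 3 and fell in 1 of 21, 6 and 1 adjusted over the list alone (adjusted p = 0.0323, and 0.533 with an estimated correlation). With the offset 1 MHC class I gene rose and 1 fell, and the list was at 0.476. No list call of this comparison held with an estimated correlation.

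The test called 1710 genes, 1077 up and 633 down, 37 and 49 of them at least 2 times apart. The GC content and length offset gave 253, 133 up and 120 down. Other settings gave 555 with a length offset, 3308 with DESeq2 and 3377 without the filter on low counts. The count was 9 without AB-TSEV 1, 31 without AB-TSEV 2, 871 without ASAB 1 and 15 without ASAB 2. With the offset it was 24 and 105 without AB-TSEV 1 and 2, and 42 without ASAB 2. KLHL11, a ubiquitin ligase adaptor gene (chromosome 17, 41853545 to 41865431), fell to 1.37 from 3.94 CPM (log2 fold change -1.52, adjusted p = 0.0033, and 0.00369 with the offset). ZBED6 (-2.12) and ADORA2A (1.07) kept their calls with the offset at 0.0371 and 0.0437. HYPK (-1.76), ENSG00000284906 (-1.56), FAM167B (1.13), NPIPA9 (0.96) and ADAT3 (0.95) lost theirs, and of these HYPK overlaps SERF2, NPIPA9 has near-identical copies and ADAT3 overlaps SCAMP4.

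**Figure D3:**
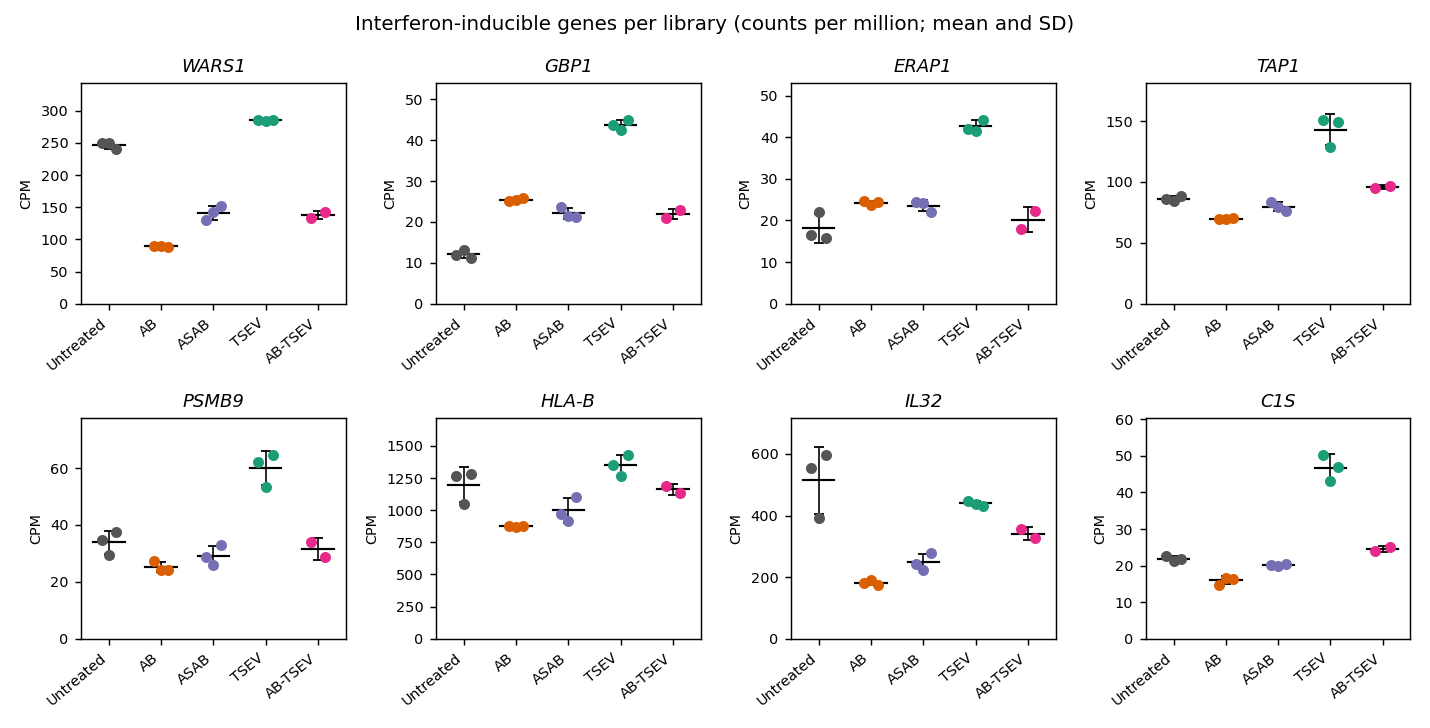
CPM of WARS1, GBP1, ERAP1, TAP1, PSMB9, HLA-B, IL32 and C1S in the 5 groups, with points for libraries, mean and SD; these genes were picked after their values were seen. TSEV lies above the other groups for ERAP1, with 42.6 CPM against 18.1 to 24.2, whereas Untreated is highest for IL32, with 515 CPM against 439 in TSEV.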

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

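The tests in this part were chosen only after the result was seen, apart from the gene lists themselves. The change that comes with the antibody was compared between vesicles and cells without vesicles. A difference here cannot be told apart from a difference between library sets, as given below. The change from TSEV to AB-TSEV was set against the change from Untreated to ASAB in a test of the difference itself (edgeR). It called 8480 genes, 4381 with a positive and 4099 with a negative difference. The count ranged from 6288 without AB-TSEV 1 to 9938 without Untreated 2. With the GC content and length offset it was 7240, of which 4675 were shared in direction.

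Stress response genes were among those with a positive difference. Their median difference was 1.12 on the log2 scale, with 18 of 24 members called positive and 0 negative. The median change was -1.38 from Untreated to ASAB and -0.01 from TSEV to AB-TSEV. The state of the untreated cultures, which had no mock treatment, is an open explanation of the first value. With the offset the median difference was 1.10, and the change from TSEV to AB-TSEV was -0.22.

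This contrast sets libraries with sheet numbers 27 to 31 against numbers 1 to 9 in each of the changes compared, with opposite signs, so a difference between the sets enters it 2 times over and cannot be told apart from it. Groups of 2 or 3 libraries are too small to test single libraries as outliers.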

How the results depend on the processing

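Under RLE factors, coding genes only and no filter, every comparison's count stayed within 1.5 times, except AB-TSEV against ASAB (1710 genes) without the filter, with 3377. That count was 3308 with DESeq2, 555 with a length offset and 3507 with a replicate block. Other counts moved in AB-TSEV against Untreated (4988), with 2571 in a fit of its groups only, and AB-TSEV against TSEV (3825), with 1234 under a block by tube number. The fit of only the compared groups has fewer libraries to judge spread. For the rest the cause was not tested.

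Leaving out each library gave 9 to 1240 genes in AB-TSEV against ASAB, with 9 and 31 without AB-TSEV 1 and 2, 15 without ASAB 2 and 871 without ASAB 1. It gave 17 to 2995 in AB-TSEV against TSEV, with 17 and 1622 without AB-TSEV 1 and 2, 443 without TSEV 2 and 589 without TSEV 3. In AB-TSEV against Untreated it gave 2635 to 6209, with 2635 and 3144 without AB-TSEV 1 and 2. A lone AB-TSEV library is assumed to vary like the other groups.

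The next choices were added after seeing the data. With Untreated 2 and ASAB 3 left out, the counts were 7577 in AB-TSEV against Untreated, 7158 in ASAB against AB (4766), 7486 in AB-TSEV against TSEV, 6089 in AB-TSEV against ASAB and 7809 in TSEV against AB (5188). With the GC content and length offset they were 7670 in AB-TSEV against Untreated, 7472 in ASAB against AB, 1118 in AB-TSEV against TSEV and 253 in AB-TSEV against ASAB. On data simulated with such a trend for AB-TSEV against ASAB, 1222 unchanged genes were called without the offset and 8 with it. The offset removes the same trend that was laid over these data, so the drop to 8 follows from the setup. The 1222 calls show only that such a trend can by itself yield calls. They do not tell whether the trend in the real libraries is technical. The cause was not tested for any of these counts.

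The 3036 genes shared by all 4 treated groups were 1780 with fits of the compared groups only, 5234 with Untreated 2 and ASAB 3 left out and 5155 with the offset. They were 2403, 4388 and 2459 without Untreated 1, 2 and 3. No split of Untreated keeps 2 libraries on each side, so separate controls could not be formed. List calls, 100 with the preset correlation, were 40 with an estimated one, 153 with fry and 108 with the offset. Fry asks another question, whether a list moves on balance, without comparing it with other genes.

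Of 938 named genes in their comparisons, 934 kept call and direction with RLE factors, 925 with DESeq2, 915 without the filter, 838 with the length offset, 827 with the block by tube number and 778 with the GC content and length offset. Of 317 in the comparisons of AB-TSEV, 110 and 188 did without AB-TSEV 1 and 2. Directions reversed for BRCA2 in AB-TSEV against ASAB with the length offset (0.118). With the GC content and length offset CD68 (0.070) and KRT7 (0.013) reversed in TSEV against Untreated. XIAP (0.099), ATF6 (0.069), DGAT1 (-0.016), CTSZ (-0.006) and UQCRC1 (-0.031) reversed in AB-TSEV against TSEV, and IRF7 (-0.003), XIAP (0.005), PKP3 (-0.027), HGS (-0.017) and CD81 (-0.002) in AB-TSEV against ASAB. Cytosolic ribosomal proteins reversed in ASAB against AB under the block by tube number (adjusted p = 0.581), and the nuclear respiratory chain in ASAB against Untreated with Untreated 2 and ASAB 3 left out (adjusted p = 0.972). The cause was not tested.

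Whether replicate numbers mark paired libraries stays open. By title number, the median correlation of deviations from the group mean was 0.022 for same-numbered pairs and -0.01 for other pairs. Correlations of same-numbered libraries ran from -0.102 to 0.203 over 26 pairs by title, with 5 over 0.1 and 11 of 14 libraries correlating best with their own number, and from -0.105 to 0.158 over 16 pairs by tube. The block by title number gave 3507 genes in AB-TSEV against ASAB, against 1710 without it, and moved no other count by more than 1.5 times. At the depth and spread of these libraries together, edgeR recovered 0 of 50 simulated genes changed 1.2 times in AB against Untreated and 0 of 50 in AB-TSEV against Untreated. In the simulation for AB-TSEV against ASAB it recovered 11 of 50, and 19 with the offset. Depth alone was not varied.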

Other observations

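Vesicles alone and the anchored antibody differed in few genes, most of them higher with vesicles and many of them interferon targets. TSEV against ASAB was compared only after the data were seen, and it stays within a library set. C1S, a protease of the complement cascade, had 46.8 ± 3.59 CPM in TSEV and 20.2 ± 0.214 in ASAB (log2 fold change 1.22, adjusted p = 6.27e-07), higher in 3 of 3 libraries. WARS1 (1.01), GBP1 (0.98), the peptide transporter gene TAP1 (0.85) and PSMB9 (1.05) were higher too, with IL6 (0.98) and the complement gene C3 (0.98). The carboxypeptidase gene CPA4 was lower (-0.83). These genes were chosen after their values were seen. Interferon-gamma genes rose in 6 of 19 cases (median 0.54, adjusted p = 1.12e-06 with an estimated correlation), MHC class I genes in 8 of 21 (8.3e-05), NF-kB genes in 4 of 27 (0.00345) and type I interferon genes in 2 of 27 (0.000387). The edgeR test called 47 genes, 42 up and 5 down, of 869 at an unadjusted p under 0.05. DESeq2 called 106 and the fit with the GC content and length offset 145, of which 46 were shared. Without TSEV 1 the count was 29.

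Other gene groups give a fuller view of the free antibody against Untreated. Unfolded protein response genes were divided, with 14 up and 6 down of 20 (adjusted p = 0.463), XBP1 falling to 50.2 ± 0.303 from 153 ± 4.22 CPM. Hypoxia and glycolysis genes were divided too, 10 up and 8 down of 30 (adjusted p = 0.885), with VEGFA at 17.4 ± 1.3 against 130.1 ± 11.7 CPM and LDHA at 1127 ± 20.1 against 509.6 ± 11.9. Vesicle and endosome genes rose in 13 and fell in 4 of 25 (adjusted p = 0.0418, and 0.256 with an estimated correlation), CLTC among them. With the GC content and length offset 17 rose, at 0.0345 with an estimated correlation, and the list was also called up in ASAB, TSEV and AB-TSEV against Untreated (0.0223, 0.0219 and 0.0271). Lysosome genes rose in 7 and fell in 13 of 23 (adjusted p = 0.689). Cytosolic ribosomal protein genes fell in 30 of 38 (adjusted p = 0.00359, and 0.950 with an estimated correlation) and nuclear respiratory chain genes rose in 12 and fell in 1 of 32 (0.023, and 0.950), with 27 up under the offset. Mitochondrially encoded genes rose in 7 and fell in 1 of 13 (0.00501, and 0.627). The offset ended the list call (0.172) but still gave 7 up and 1 down, with a median of 0.42. NRF2 targets rose in 9 and fell in 6 of 22 (0.885), with PRDX1 at 549 ± 12.6 against 188 ± 23.2 CPM, and apoptosis regulators in 13 and 9 of 33 (0.989, with a median of 0.10 and a mean of -0.17).

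Surface and identity genes moved in both directions. Tumour surface antigens rose in 6 and fell in 8 of 21 (adjusted p = 0.974), with mesothelin (MSLN) at 234 ± 5.06 against 437 ± 77.1 CPM. PVR, a ligand of lymphocyte receptors, fell to 92.0 ± 1.82 from 219 ± 11.5 CPM and MICB, a ligand of NKG2D, rose by 0.64. Mesenchymal genes rose in 8 and fell in 11 of 28 (0.989). Of the marker lists, fibroblast genes gave 1 rise and 1 fall of 4 (COL1A1 at 622 ± 22.0 against 209.9 ± 17.7 CPM), endothelial 1 and 2 of 6, B cell 0 and 3 of 4, monocyte 0 and 2 of 4, T cell 1 and 1 of 7 and cytotoxic 0 and 2 of 3, all at an adjusted p of 0.5 or more. Replication-dependent histones gave 3 rises and 4 falls of 25 (0.989) and long noncoding RNA 4 and 5 of 11 (0.885), with GAS5 at 124 ± 2.45 against 299 ± 38.6 CPM.

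The tests in the next 3 paragraphs were chosen after the results were seen. The fall of stress response genes in all 4 treated groups may reflect the treatments or the state of the untreated cultures. The library sets are argued against, since AB-TSEV against Untreated, within a set, had a median of -1.51. The GC content and length of genes are argued against as well, since the highest of the 4 medians with the offset was -1.23. The state of the untreated cultures stays open. In 24 of 24 members the 3 Untreated libraries lie above all 11 treated ones, and no group received a mock treatment.

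The higher interferon genes in TSEV may come from signalling in the cells. The lower of the medians of the interferon-gamma list against AB and ASAB, within the library set, was 0.54, and the smallest rise with the offset was 0.4, so library set and GC content and length of the genes are argued against. T cell RNA that holds the marker genes is argued against too. Vesicle RNA without these markers was not tested. Summed T cell markers rose by 0.338 CPM from AB to TSEV. This was 0.173% of the rise of WARS1, the interferon-gamma list member with the smallest p (196 CPM). Part of that WARS1 rise reflects a level in AB below Untreated. Against ASAB, where the median of the interferon-gamma list was 0.54, summed T cell markers were 1.88 ± 0.234 CPM in TSEV and 1.87 ± 0.0938 in ASAB. IFNG had no read. The interferon-gamma list rose more than the type I list against AB, by 0.64 (two-sided permutation p = 0.00217 over 19 and 27 genes, which are not independent replicates). In AB against Untreated, where the library set changes too, the medians were -0.43 for interferon-gamma and 0.51 for type I, a difference that was not tested. In TSEV against Untreated they were 0.41 and 0.38, so which interferon may act stays open.

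FOS, FOSB, EGR1 and the NF-kB genes were lower in AB than in ASAB and TSEV. The lower of both NF-kB medians was 0.78 within the library set and 0.78 with the offset, which argues against library set and GC content and length. Handling of the AB wells at harvest could also do this and stays open. Over FOS, FOSB and EGR1 the lowest library of the other groups was at least 10.4 times the highest AB library, and such genes answer to handling within minutes. The stress response, cholesterol, G1/S and heat shock lists also set AB apart from both ASAB and TSEV, and handling was not weighed for them.

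Splits of the 6 libraries of a comparison into groups of 3 number 10, too few for a share under 0.05. Every split but the real one mixes both groups on each side, so a difference between the groups counts there as spread. Low counts are then likely, whatever made the groups differ, and say nothing of the cause. The first 5 comparisons named here were planned for this before the data were examined. With edgeR, the highest other split called 0 genes against 10861 in AB against Untreated, 0 against 8739 in TSEV against Untreated, 0 against 4766 in ASAB against AB and 1 against 5188 in TSEV against AB. In each, 1 split, the real one, gave as many genes. In ASAB against Untreated (8196) the split of ASAB 1, ASAB 2 and Untreated 2 against the rest called 2044 genes, which points to a structure of the samples. For TSEV against ASAB, added later, it was 0 against 47.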
